A study of Arabidopsis thaliana with 9 samples.

How the data were processed

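RNA was measured by sequencing in stems and leaves of soil-grown, wild-type Arabidopsis thaliana seedlings (2 weeks old per the labels). The 9 libraries form 3 groups of 3: control (day 0), cold once (day 1) and repeated cold (4 cycles, day 4). A cold cycle was 6 h at 4 °C and 18 h at room temperature, applied 1 or 4 times. The labels add 6 h at 0 °C after the cycles and leave open whether plants were sampled before or after that step. Per the labels' protocols, 0.5 µg of total RNA from a Qiagen RNeasy kit went into SMARTER mRNA-Seq libraries. Groups were taken from the sample labels. Day, and with it plant age, differed with group in every comparison. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples.

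The deposited table gives FPKM (fragments per kilobase of gene model, scaled to library size) computed by the authors for 25320 genes, with 1 column per library and no log transformation. TopHat, Cufflinks and Cuffdiff are named in the submitters' processing notes, without version, role or order. Strandedness and genome build are not stated there. Gene starts and ends in the table equal those of TAIR10.1 for 25082 of the 25087 loci found in that annotation (99.98%), and positions are given on that build. The unit was assumed to be FPKM before the data were examined and was then checked on the values: low values of a library lie on steps that scale with 1 over gene length, and column sums are unequal. Whole reads could be recovered from these steps for 24959 genes (98.6%) in all libraries, with a tolerance of 0.01 read. Depth, the library size implied by these steps, was 17.98 to 21.49 M reads per library. Recovered reads summed over genes to 99.14% to 99.53% of it. A gene near FPKM 1 had a median of 32 reads, a counting error of 17.7%. A value of 0 allows up to 3 reads, or 0.14 to 0.167 FPKM for a gene of 1 kb. These errors and floors cover counting only, since the reads carry no molecular identifiers in the table.

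FPKM values were used without further scaling, as log2(FPKM + 1). Genes with FPKM of at least 1 in at least 3 of the 9 libraries were kept (17740 genes). A linear model with 1 mean per group was fitted to all 9 libraries with limma 3.58.1 (lmFit, eBayes with a mean trend, prior degrees of freedom 3.21) in R 4.3.3. The 3 pairwise comparisons were tested with limma's moderated test and any difference among groups with its moderated F-test. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Log2 changes are differences of group means on the log2(FPKM + 1) scale with the model's standard error, and folds are ratios of mean FPKM.

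The tests, the filter, the gene lists, the naming rule and the first set of alternatives were chosen before the data were examined. The naming rule took, for each comparison, the 8 largest rises and the 8 largest falls among called genes of the nuclear genome with mean FPKM of at least 5 in the higher group and no overlap between the libraries of both groups. It added up to 4 members of each list with the smallest p, up to 6 genes per response class, CBF1, CBF2, CBF3, COR15A, RD29A, and the H3K4 genes as a group. A gene outside the rule is marked where it is named. The 19 lists cover CBF pathway regulators, cold-regulated effector genes, the circadian clock, nuclear photosynthesis genes, redox and photoprotection, abscisic acid, heat shock, salicylic acid and immunity, jasmonate, flavonoids and anthocyanins, sugar, proline and starch, H3K4 methyltransferases and demethylases, Polycomb with vernalization and flowering, growth, touch and rapid stress, ribosome biogenesis, root markers, flower and seed markers, and reference genes. They hold 252 genes, of which 244 were matched by locus identifier and 227 passed the filter. The other 8 (HSFC1, HSP21, MYC2, F3H, LRX1, RHD6, CRU3 and SESA3) were not analysed here. Lists were tested against the other genes with limma's camera at a preset correlation of 0.01, with an estimated correlation beside it, and counted a second time with p-values adjusted over the list alone. The planned limma test fry, which takes the genes of a list without the other genes, was run beside camera. Overlaps were set against 20 simulations of unchanged groups that share the same libraries and against the product expected from independent lists. Enrichment of Gene Ontology terms was added after the data were seen, with 11948 annotated, tested genes as background and 695 terms of 10 to 500 genes.

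The procedure was tested on simulated reads drawn from the real means and depths with 17439 genes passing the filter. In the simulated comparison of cold once with control, 23.9% of genes changed 1.5-fold, 60.6% of those changed 2-fold and 87.9% of those changed 4-fold were called, and 5% of calls were false. For repeated cold against control the shares were 16.4%, 61.2% and 87.9%, with 4.35% false. For repeated cold against cold once they were 26.1%, 68.4% and 92.4%, with 6.06% false. Few genes were changed in the simulation: 17240 of 17439 were left unchanged between cold once and control. Calls were far more numerous in the real comparisons with control, so these shares need not carry over to them.

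Alternatives were other pseudocounts (0.1 and 5), no filter or a minimum of 5 FPKM, median-of-ratios scaling (size factors 0.94 to 1.11), quantile normalization, the replicate number as a block, only the 6 libraries compared, no mean trend, a minimum change of 1 on the log2 scale, and leaving out each library in turn. Added after the data were seen were limma voom on recovered reads, reads thinned to 1 total, a floral marker score or an immunity gene score as a covariate, and a recount of the response classes under each setting. Near-identical copies (CBF1 to CBF3, KIN1 and KIN2, the LHCB1 and RBCS families, ELIP1 and ELIP2, the PDF1.2 family) share reads in ways the authors' counting may have split differently, so their single values are uncertain. The same holds for genes that overlap another gene, 6202 in the table, because strand use is not stated.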

Results

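Transcript levels were measured in 9 libraries from stems and leaves of wild-type Arabidopsis seedlings, 3 libraries in each of 3 groups. Control plants were sampled at day 0 at room temperature or before stress. Cold-once plants (day 1) had passed through 1 cycle of 6 h at 4 °C and 18 h at room temperature, and repeated-cold plants (day 4) through 4 such cycles. The labels add 6 h at 0 °C and leave open whether sampling came before or after it. Depth was 20.05 to 21.49 M reads in control, 20.18 to 20.48 M in cold once and 17.98 to 20.78 M in repeated cold. The series concerns the histone mark H3K4me3 in the memory of low temperature. The comparisons with control ask what differed after 1 or 4 cycles, and that of repeated cold with cold once whether repetition gave another level. If sampling followed the 0 °C step, that step and the cycles cannot be told apart against control, which lacked both. Log2 changes are given with their standard errors on the log2(FPKM + 1) scale and levels as mean FPKM with SD, with n = 3 libraries per group throughout.

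Libraries separated by group. The first principal component held 65.2% of the variance, with control libraries between -69.28 and -65.06, repeated-cold libraries between 22.47 and 28.09, and cold-once libraries between 38.78 and 47.77. Among 17740 genes tested, 8762 differed among the 3 groups by limma's F-test. The median gene lay at -0.16 in cold once against control, -0.10 in repeated cold against control and 0.06 in repeated cold against cold once. Median-of-ratios scaling moved these medians to -0.01, 0.01 and 0.00, so list medians are given relative to the median of all genes.

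**Figure D1:**
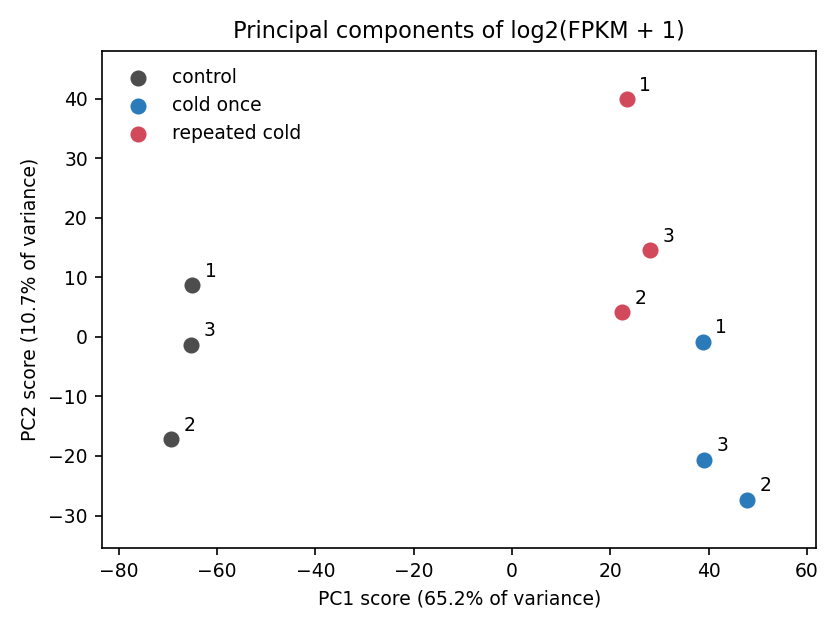
Scores of the 9 libraries on the first and second principal components of log2(FPKM + 1), coloured by group and numbered by replicate. On PC1 the repeated-cold libraries (22.47 to 28.09) lie between control and cold once, nearer to cold once. On PC2 they lie above the cold-once libraries.

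Cold-once plants had high levels of the CBF genes, the transcription factors that switch on cold-responsive genes. Whether the cycle or the 6 h at 0 °C raised them was not tested. CBF2 (chromosome 4, 13015250 to 13016235) stood at 8.08 ± 1.87 FPKM in control and 910 ± 186 in cold once, a log2 change of 6.65 ± 0.19 (adjusted p = 9.43e-08). CBF1 (chromosome 4, 13021780 to 13022996) rose by 5.01 ± 0.37 and CBF3 (chromosome 4, 13018010 to 13019400) by 5.51 ± 0.16, although CBF3 overlaps AT4G07385 on the other strand. The rise of RVE2 (chromosome 5, 14751344 to 14753088), a MYB-like factor related to the clock genes CCA1 and LHY, was larger still, to 541 ± 31.6 FPKM in cold once (7.63 ± 0.12). CCL, encoding a CCR-like protein (chromosome 3, 9827682 to 9828917), fell from 1350 ± 139 to 46.2 ± 2.88 FPKM (-4.83 ± 0.11).

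In all, 9278 of 17740 genes tested were called in cold once against control, 3314 higher and 5964 lower (64.3% lower). List counts in each comparison are to be read beside its calls among all genes, which were frequent against control. Under median-of-ratios scaling 8968 were called, 4536 higher and 4432 lower (49.4% lower), so the split depended on scaling. Besides RVE2 and CBF2, the largest rises were those of AT4G18422, an uncharacterized protein (7.32 ± 0.20), the Dof-type zinc finger gene AT1G26790 (6.67 ± 0.22), the early light-induced genes ELIP2 (6.42 ± 0.19) and ELIP1 (5.67 ± 0.22), the EXORDIUM LIKE 1 gene AT1G35140 (6.07 ± 0.35) and CBF4 (5.85 ± 0.69). The strongest falls after CCL included AT1G15125, a methyltransferase gene that overlaps AT1G15120 (-4.37 ± 0.67), the F-box gene AT1G80440 (-4.33 ± 0.23), CID2 (-4.23 ± 0.20), the senescence-associated STR15 (-4.23 ± 0.28), the linker histone gene HIS1-3 (-4.16 ± 0.23), DJC76 (-4.10 ± 0.21) and AT4G01390 (-4.08 ± 0.46), which overlaps AT4G01370.

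Of 15 CBF pathway regulators tested, 9 rose, 1 fell and 5 were not called (10 and 1 adjusted over the list alone). ZAT12, a zinc finger factor of stress responses, rose by 3.49 ± 0.31 and RAV1 by 1.22 ± 0.12, whereas CAMTA3, a calmodulin-binding activator of CBF genes named here after its value was seen because it was the single fall, fell by 0.97 ± 0.16. The list's median lay 0.91 above that of all genes (camera adjusted p = 5.69e-05, and adjusted p = 0.211 with an estimated correlation). Among 20 cold-regulated effector genes 13 rose and 2 fell (the same counts adjusted over the list alone), with a median 1.52 above all genes (adjusted p = 1.79e-04, and adjusted p = 0.498 with an estimated correlation). BAM3, a plastid beta-amylase, went from 56 ± 5.31 to 880 ± 87.7 FPKM (3.95 ± 0.11). The dehydrin genes ERD10 and COR47 rose by 1.84 ± 0.15 and 1.37 ± 0.14, and RD29A by 1.49 ± 0.29 (adjusted p = 0.00217). COR15A, a chloroplast-protecting protein gene, was at 134 ± 70 FPKM in control and 204 ± 20.8 in cold once and was not called (0.74 ± 0.35, adjusted p = 0.106). COR413IM1, for a chloroplast inner-membrane protein, fell from 137 ± 3.2 to 14.8 ± 1.51 FPKM.

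**Figure D2:**
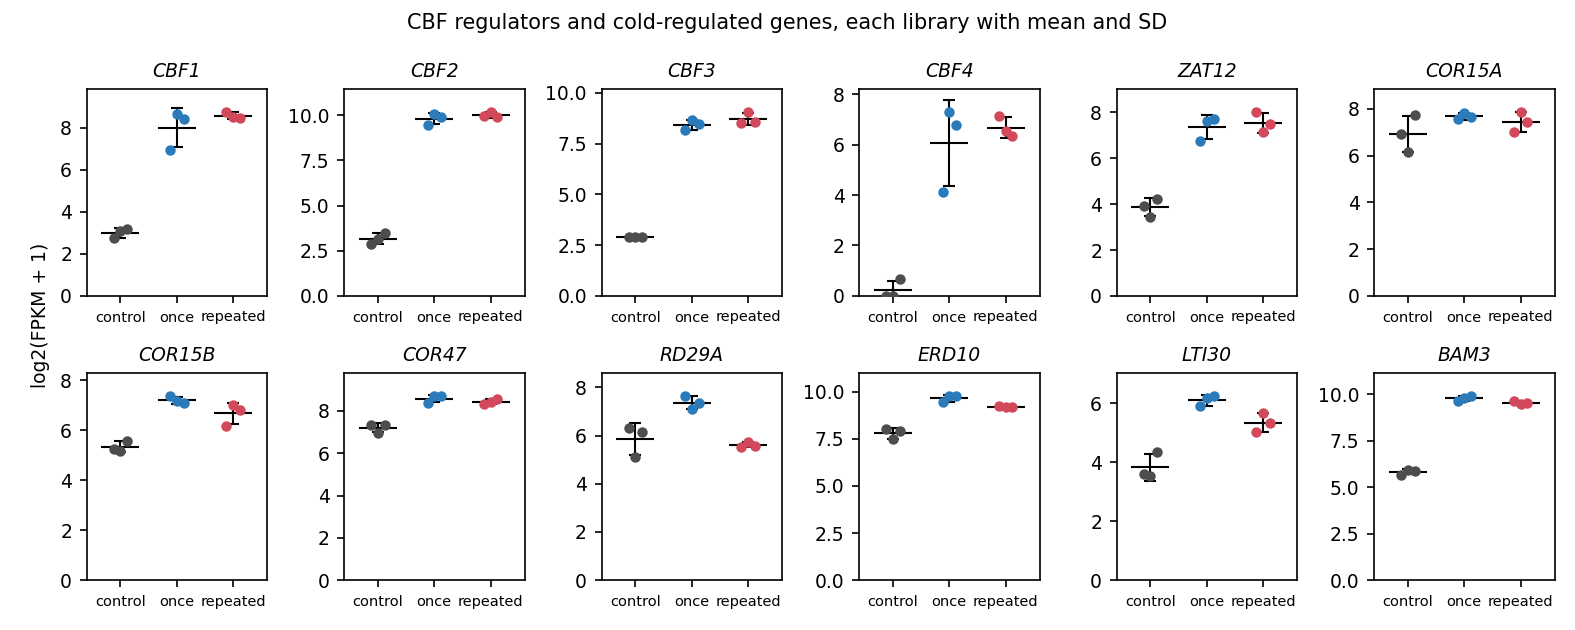
Levels of 12 CBF pathway and cold-regulated genes as log2(FPKM + 1), each point a library, with the group mean (bar) and SD. CBF2 stood at 8.08, 910 and 1040 FPKM in control, cold once and repeated cold, and RD29A at 60.8, 164 and 48.2.

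Clock genes moved in both directions, 9 of 18 higher and 5 lower (9 and 6 adjusted over the list alone), with a median 0.74 above all genes (camera adjusted p = 0.00482, and adjusted p = 0.519 with an estimated correlation). The dawn-phased LHY rose from 3.69 ± 1.05 to 182 ± 8.14 FPKM (5.31 ± 0.18), RVE1 by 4.37 ± 0.13 and CCA1 by 3.61 ± 0.15. Under quantile normalization the clock list was no longer called. Of 20 nuclear photosynthesis genes, 5 rose and 11 fell (the same adjusted over the list alone), but with median-of-ratios scaling 6 were higher and 4 lower, and with quantile normalization 6 and 8. RBCS1B, a small subunit of Rubisco, rose from 275 ± 51.1 to 1510 ± 102 FPKM and RBCS2B by 1.95 ± 0.15, although near-identical RBCS copies share reads. LHCA3, a light-harvesting protein of photosystem I, fell by 0.91 ± 0.12. Among 11 redox and photoprotection genes 4 rose and 3 fell (4 and 4 adjusted over the list alone). The catalase gene CAT2 rose by 2.24 ± 0.16 and CAT3 fell from 1910 ± 53.7 to 145 ± 28.2 FPKM.

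**Figure D3:**
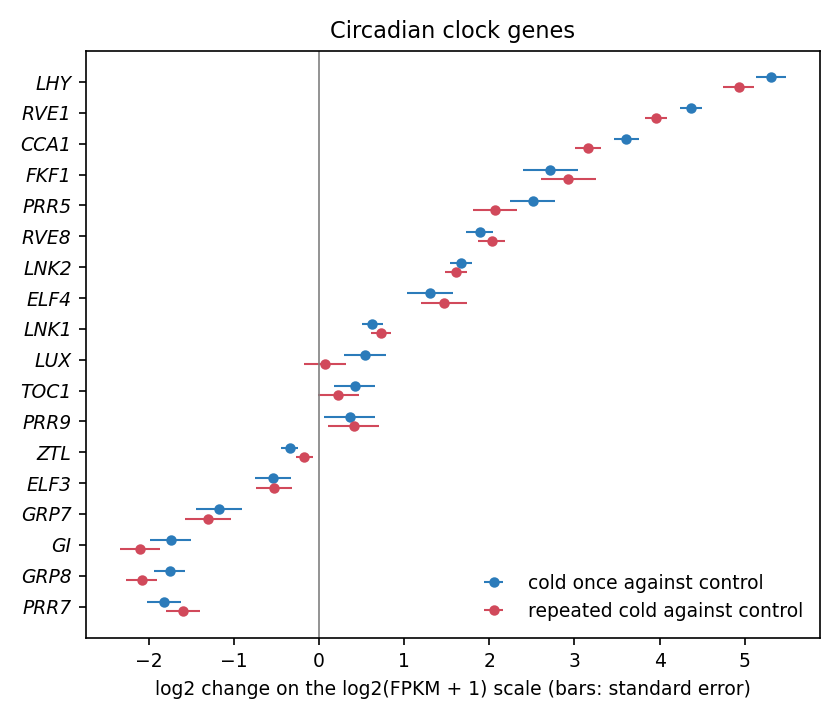
Log2 change of 18 circadian clock genes against control with its standard error, for cold once and repeated cold. LHY was highest in both (5.31 and 4.93), and the fall of ZTL in cold once (-0.34) was not called under either scaling alternative.

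Of genes of flavonoid synthesis, 9 of 14 were higher and 2 lower (11 and 2 adjusted over the list alone), with a median 1.05 above all genes (adjusted p = 8.66e-04, and adjusted p = 0.519 with an estimated correlation). TT4, chalcone synthase, went from 45.4 ± 14.5 to 370 ± 46.7 FPKM (3.05 ± 0.24) and TT5, chalcone isomerase, rose by 1.89 ± 0.18. PAP2, a MYB activator of anthocyanin genes, fell by 1.58 ± 0.24. Under either scaling alternative 11 flavonoid genes were higher and 1, PAP2, lower. Of 8 ribosome biogenesis genes 5 rose and none fell (6 adjusted over the list alone), with a median 0.74 above all genes (adjusted p = 0.00142, and adjusted p = 0.519 with an estimated correlation). The fibrillarin gene FIB2 rose by 1.37 ± 0.15 and RPS6A by 1.00 ± 0.11. NUC-L1 of that list was lower under quantile normalization only. For the 14 other lists camera's adjusted p lay between 0.0988 and 0.908. Within the abscisic acid list 4 of 12 rose and 4 fell (the same adjusted over the list alone). CYP707A1, which breaks down abscisic acid, rose by 2.77 ± 0.21 and the transcription factor genes ABF4 and RD26 fell, ABF4 by 0.98 ± 0.10 and RD26 from 48.8 ± 9.85 to 19 ± 2.24 FPKM. Sugar, proline and starch genes gave 5 higher and 4 lower of 10 (the same adjusted over the list alone), among them ERD5, proline dehydrogenase (2.52 ± 0.25), and SEX1, a starch-degrading dikinase (-2.37 ± 0.17).

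Of 8 heat shock genes 3 rose (3 adjusted over the list alone). DREB2A, a dehydration and heat factor, rose by 3.07 ± 0.32, while HSP101 and HSP90.1 (0.83 ± 0.25 and 1.17 ± 0.36) lost their calls without control replicate 2 or cold once replicate 3 (adjusted p up to 0.0768 and 0.073). Of 8 touch and rapid stress genes 4 rose and 2 fell (the same adjusted over the list alone), including TCH4, a cell wall enzyme gene (3.28 ± 0.23), and CML38 (2.37 ± 0.45). Of 12 jasmonate genes 1 rose and 5 fell (the same adjusted over the list alone): JAZ1, a repressor of jasmonate signalling, rose by 1.29 ± 0.25 and OPR3, of jasmonate synthesis, fell by 1.12 ± 0.18. With median-of-ratios scaling these counts became 2 and 3, and with quantile normalization 2 and 4. Growth genes gave 1 higher and 4 lower of 11 (the same adjusted over the list alone). EXPA8, an expansin, fell from 47.2 ± 25.5 to 2.94 ± 1.17 FPKM and PIF4, a growth-promoting factor, by 2.00 ± 0.13. Among 14 salicylic acid and immunity genes none rose and 3 fell (1 adjusted over the list alone). WRKY33 fell by 1.42 ± 0.31. The falls of NPR1 (-0.53 ± 0.17) and FRK1 (-1.13 ± 0.40) were not called under either scaling. NPR1 also lost its call without control replicate 1 or 3 or cold once replicate 2 (adjusted p up to 0.0793), and FRK1 without control replicate 1 or 3, cold once replicate 2 or 3, or repeated cold replicate 2 or 3 (up to 0.139).

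Few genes for enzymes that write or erase H3K4 methylation were called. Of 19 tested, none rose and 3 fell (3 adjusted over the list alone), namely the complex subunit RBL (-0.84 ± 0.14) and the demethylases JMJ14 (-0.50 ± 0.12) and JMJ18 (-0.64 ± 0.14). With either scaling the same number fell and 2 rose, SDG4 and WDR5A, both named after their values were seen. Polycomb, vernalization and flowering genes gave 3 higher and 1 lower of 10 (the same adjusted over the list alone), and 5 higher and 1 lower under either scaling. The flowering signal gene FT was at 0.669 ± 0.092 FPKM in control and 2.76 ± 0.582 in cold once (1.16 ± 0.26), and SOC1 fell by 0.85 ± 0.20. The other rises, of the Polycomb genes CLF (0.54 ± 0.17) and FIE (0.31 ± 0.10), were lost without control replicate 1 or cold once replicate 1 or 2, that of CLF also without control replicate 2 or cold once replicate 3 and that of FIE without control replicate 3 (adjusted p up to 0.0876 and 0.096). Of 2 root marker genes tested, NRT2.1 rose by 1.02 ± 0.23 and BGLU23 was not called (1 and 0 adjusted over the list alone).

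Flower marker genes differed between libraries within groups. SEP3, a floral organ gene, was at 2.16, 6.32 and 11.3 FPKM in the control libraries, at most 0.883 in cold once, and at 0.129, 5.12 and 0.0757 in repeated cold. It was the 1 lower call among 5 flower and seed genes (none adjusted over the list alone), and the call was lost without control replicate 2 or 3 or cold once replicate 1 or 3 (adjusted p up to 0.1). With a floral marker score as a covariate 8167 genes were called, and SEP3, HSP101, HSP90.1, VSP2, CLF and FIE were not. FRK1 was not called with an immunity gene score as a covariate. SEP3 is part of the floral score and FRK1 of the immunity score, so their own lost calls test nothing. Of 10 reference genes 3 were higher and 5 lower (the same adjusted over the list alone), but 3 and 2 with median-of-ratios scaling and 2 and 3 with quantile normalization. ACT2 rose by 0.58 ± 0.10 and UBQ10 fell by 0.49 ± 0.09. Without subtracting the median of all genes, median and mean differed in sign for the photosynthesis (-0.39 and 0.04), redox (-0.08 and 0.92), abscisic acid (-0.18 and 0.27) and sugar lists (0.38 and -0.02), with camera pointing up in each. Relative to all genes the redox median was 0.09. To complete small counts, these called list members were named after their values were seen: NCED3, BAP1, RBCS1A, RPS6B, BAM1, SUS1 and GAPC1 were higher, and COR413IM2, PRR7, GI, ZTL, GRP7, GRP8, CAT1, AOX1A, RAB18, AOS, PAP1, SPS1F, GA20OX1 and TIP41L were lower.

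CBF genes were also high in plants after 4 cycles. CBF2 reached 1040 ± 107 FPKM against 8.08 ± 1.87 in control (6.86 ± 0.19, adjusted p = 1.13e-07), CBF1 382 ± 41.2 (5.57 ± 0.37), CBF3 425 ± 92.7 (5.80 ± 0.16) and CBF4 104 ± 31.8 (6.45 ± 0.69). RVE2 was again the largest rise (7.80 ± 0.12). Among the largest falls were genes of jasmonate-linked defence: the defensin gene PDF1.2B (chromosome 2, 11089123 to 11089805) went from 518 ± 365 to 8.79 ± 3.69 FPKM (-5.37 ± 1.18, adjusted p = 0.00631) and PDF1.2 from 1510 ± 1110 to 48.5 ± 20.4 (-4.62 ± 1.17).

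Calls numbered 7013 in repeated cold against control, 2592 higher and 4421 lower (63% lower). Median-of-ratios scaling gave 6824 calls, 3470 higher and 3354 lower (49.2% lower). Further large rises were those of AT4G18422 (7.20 ± 0.20), AT1G26790 (6.35 ± 0.22) and AT1G70640, for a PB1 domain protein (5.24 ± 0.24). Large falls beside the defensins were those of AT1G15125 (-5.21 ± 0.67), AT4G16260, a putative glucanase (-4.62 ± 1.04), and STR15 (-4.48 ± 0.28). PDF1.2C (-5.27 ± 1.53), VSP1, a vegetative storage protein (132 to 8.4 FPKM), and the acyltransferase gene ACT (-4.20 ± 1.18) also fell, with calls that depended on which libraries were used. PDF1.2C lost its call without control replicate 2 or 3 or repeated cold replicate 2 or 3 (adjusted p up to 0.0748), VSP1 without repeated cold replicate 3 (0.0506) and ACT without control replicate 2 or 3 or repeated cold replicate 1 or 3 (up to 0.0678).

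As a list, 9 of 12 jasmonate genes fell and 1 rose (the same adjusted over the list alone), with a median at -1.47 relative to all genes (camera adjusted p = 0.0353, and adjusted p = 0.873 with an estimated correlation). VSP2 fell by 3.58 ± 0.71, OPR3 by 1.63 ± 0.18 and AOC1 by 2.05 ± 0.30, and JAZ1 rose (adjusted p = 0.00353). The list's call was lost without repeated cold replicate 1, 2 or 3 (adjusted p up to 0.0713). It was also lost with a pseudocount of 5, a minimum of 5 FPKM or the replicate number as a block. Flower markers had a median at -1.20 relative to all genes, with none called. With a floral marker score as a covariate VSP1 and PDF1.2C were not called, whereas PDF1.2, PDF1.2B, OPR3, AOC1 and JAZ1 were. Among CBF pathway regulators 9 of 15 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 1.57e-05, and adjusted p = 0.167 with an estimated correlation). Of 20 cold-regulated effectors 11 rose and 3 fell (the same adjusted over the list alone), with adjusted p = 0.00523, and adjusted p = 0.682 with an estimated correlation. BAM3 rose by 3.72 ± 0.11, ERD10 by 1.40 ± 0.15 and AZI1, a lipid-transfer protein of defence priming, by 2.68 ± 0.32. RD29A was at 48.2 ± 3.64 FPKM against 60.8 ± 24.3 in control (-0.24 ± 0.29, adjusted p = 0.537) and COR15A at 177 ± 53 (0.50 ± 0.35, adjusted p = 0.292). Clock genes gave 9 higher and 4 lower of 18 (9 and 5 adjusted over the list alone), with adjusted p = 0.0101, and adjusted p = 0.682 with an estimated correlation. LHY rose by 4.93 ± 0.18 and RVE1 by 3.96 ± 0.13. Of 8 touch genes 5 rose and none fell (5 and 1 adjusted over the list alone), with adjusted p = 0.0336, and adjusted p = 0.682 with an estimated correlation. TCH4 rose by 2.47 ± 0.23, and WRKY40 was called except without control replicate 1 or 2 or repeated cold replicate 1 (adjusted p up to 0.0635). The touch list was not called under either scaling or without repeated cold replicate 2 (adjusted p = 0.0885).

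For the other 14 lists camera's adjusted p lay between 0.0733 and 0.943. Photosynthesis genes gave 5 higher and 8 lower of 20 (5 and 11 adjusted over the list alone), with 5 and 4 under median-of-ratios scaling and 5 and 8 under quantile normalization. RBCS1B rose by 2.34 ± 0.14 and LHCA3 fell by 0.70 ± 0.12. Redox genes gave 4 and 4 of 11 (4 and 6 adjusted over the list alone), with ELIP2 up by 4.86 ± 0.19 and CAT3 down (-3.45 ± 0.15). Abscisic acid genes gave 4 and 3 of 12 (the same adjusted over the list alone), with RD26 at -2.05 ± 0.17. Flavonoid genes gave 4 and 2 of 14 (5 and 2 adjusted over the list alone), and 5 and 1 under either scaling, with TT4 up by 1.98 ± 0.24. Sugar, proline and starch genes gave 4 and 3 of 10 (the same adjusted over the list alone), with SEX1 at -2.11 ± 0.17. Ribosome biogenesis genes gave 5 and 1 of 8 (the same adjusted over the list alone), with RPS6A up by 0.75 ± 0.11. Growth genes gave 3 and 5 of 11 (4 and 5 adjusted over the list alone), and 4 and 2 under median-of-ratios scaling, with PIF4 at -1.52 ± 0.13 and EXPA8, at -0.95 ± 0.33, not called under either scaling. IAA19 was higher (0.52) and lost its call without control replicate 3 or repeated cold replicate 1 (adjusted p up to 0.0574). Heat shock genes gave 4 and 0 of 8 (the same adjusted over the list alone), with DREB2A up by 3.13 ± 0.32. HSP101 (0.82) and HSFA2 lost their calls without control replicate 1, 2 or 3 or repeated cold replicate 1 or 3 (adjusted p up to 0.0904 and 0.0825).

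Among H3K4 genes none rose and 3 of 19 fell (1 adjusted over the list alone), RBL by 0.57 ± 0.14. The falls of JMJ14 (-0.39 ± 0.12) and JMJ18 (-0.41 ± 0.14) were not called under either scaling, where TRO, named after its value was seen, was called higher. JMJ14 lost its call without control replicate 1 or 3 or repeated cold replicate 1 or 2 (adjusted p up to 0.0863), and JMJ18 without control replicate 1 or 3, cold once replicate 1, or repeated cold replicate 2 or 3 (up to 0.139). Polycomb and flowering genes gave 0 higher and 1 lower of 10 (the same adjusted over the list alone), SOC1 at -0.77 ± 0.20, and 3 higher and 1 lower under either scaling. Of 14 immunity genes only SARD1, an activator of salicylic acid synthesis, was called (2.07 ± 0.52, adjusted p = 0.0125, and 1 adjusted over the list alone). SARD1 varied within groups, from 38.7 to 93.2 FPKM in repeated cold and from 8.98 to 40.5 in cold once, and an immunity gene score as a covariate gave 7727 calls in all. With a floral marker score as a covariate SARD1, SOC1 and WRKY40 were not called, nor were PDF1.2C, VSP1, ACT, HSFA2, HSP101 and ACT2. Of 2 root markers NRT2.1 rose by 0.94 ± 0.23 (1 adjusted over the list alone). None of 5 flower and seed genes was called (0 adjusted over the list alone). Reference genes gave 3 higher and 4 lower of 10 (the same adjusted over the list alone), 3 and 0 under median-of-ratios scaling and 0 and 2 under quantile normalization. Calls were lost with a library left out for ACT2 (any control library, repeated cold replicate 1 or 3, adjusted p up to 0.0928), EF1A (control replicate 1, repeated cold replicate 3, up to 0.0573), PP2AA3 (any control library, up to 0.0591) and ACT8 (control replicate 2, 0.0564). On the same unshifted scale median and mean differed in sign for the photosynthesis (-0.33 and 0.06), redox (-0.42 and 0.56), abscisic acid (-0.04 and 0.20) and growth lists (0.32 and -0.02), and the abscisic acid median was 0.06 relative to all genes. Camera's direction was opposite to the mean for the photosynthesis, sugar (-0.29), H3K4 (-0.05), growth and root lists (-0.05), with no call in any of them. Called list members named after their values were seen, to complete small counts, were NCED3, BAP1, RBCS1A, RPS6B, BAM1 and GAPC1 (higher) and CAMTA3, COR413IM2, PRR7, GI, GRP7, GRP8, CAT1, AOX1A, RAB18, PAP1, PIF5, GA20OX1 and TIP41L (lower).

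Both cold responses shared most of their genes. Higher in both were 2214 genes, where independent lists would share 484, and lower in both were 4058, where independent lists would share 1486, and 4 genes, named after their values were seen, moved in opposite directions (RAP2-4, BAM6, AT3G11580 and DHAPRD). Shared calls were 67.6% of the cold-once calls (simulated unchanged groups, which hold few calls by construction, shared 0). Across genes, which are not independent replicates, the changes correlated with r = 0.91 (0.50 in simulated unchanged groups), and their covariance was 0.52 against a simulated 0.02. Both comparisons use the same control libraries, which cannot be split into parts of at least 2 libraries, so part of the excess may come from shared controls. Both cold groups also share the 6 h at 0 °C of the labels, whose part in the shared calls was not tested.

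**Figure D4:**
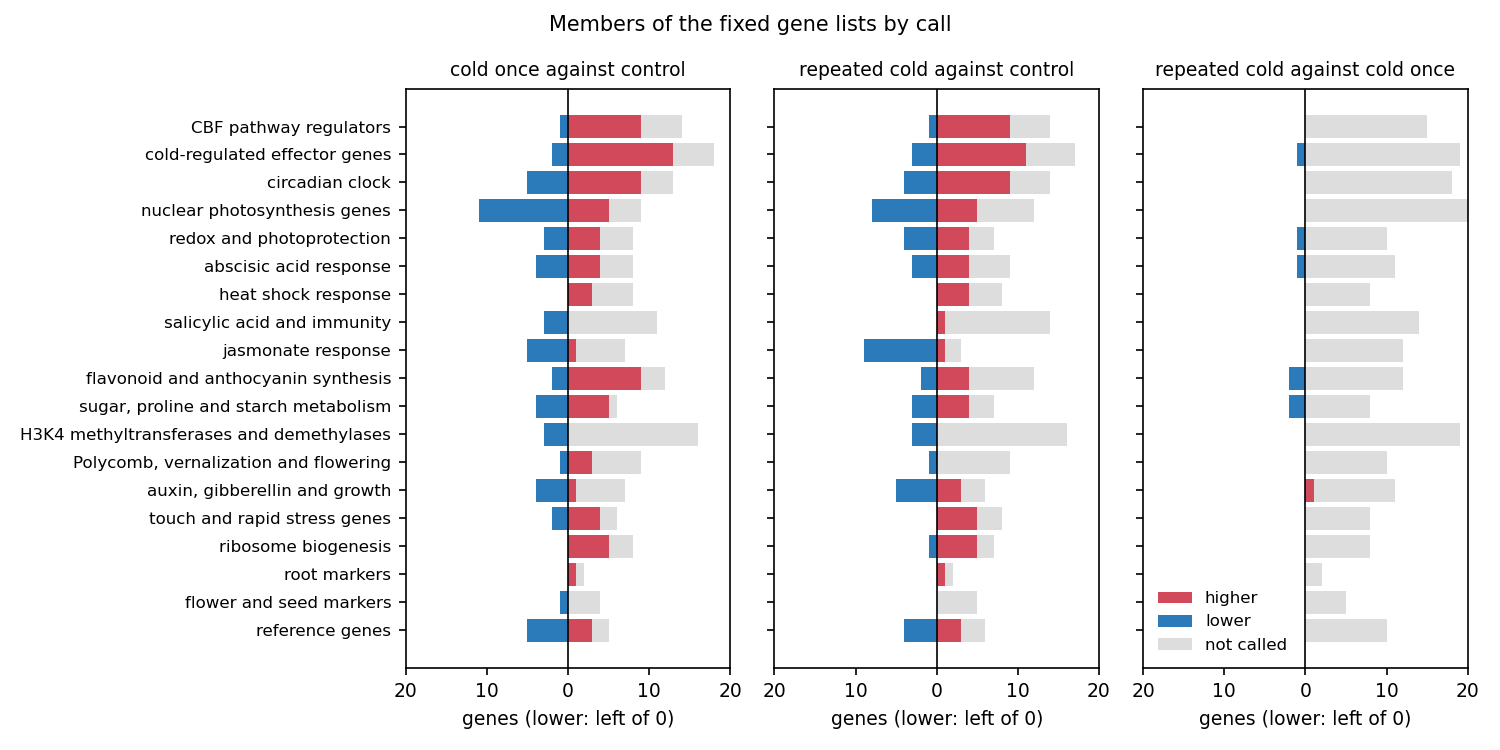
Number of tested members of each fixed list called higher (right of 0), called lower (left of 0) or not called (grey) in the 3 comparisons. In cold once, 13 of 20 cold-regulated effectors were higher, and the 11 lower photosynthesis genes became 4 with median-of-ratios scaling.

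A small set of genes was called between repeated cold and a single cycle, and most of these calls pointed back toward the control level. Part of that lean may be chance, since the cold-once libraries enter both comparisons with opposite sign. ELIP2 (chromosome 4, 8418242 to 8419325), an early light-induced protein of photoprotection, was at 0.757 ± 0.27 FPKM in control, 150 ± 31.4 in cold once and 50.2 ± 7.79 in repeated cold (-1.55 ± 0.19 in repeated cold against cold once, adjusted p = 0.0124). EXPA8 (chromosome 2, 16948791 to 16950705) rose from 2.94 ± 1.17 to 22 ± 3.34 FPKM (2.58 ± 0.33, adjusted p = 0.0126), where control stood at 47.2 ± 25.5. The expansin-like EXLA1 (chromosome 3, 16896166 to 16897308), which overlaps AT3G45980 on the other strand, fell from 168 ± 46 to 30 ± 11.3 FPKM (-2.48 ± 0.30). RD29A fell from 164 ± 31.4 to 48.2 ± 3.64 (-1.73 ± 0.29, adjusted p = 0.0314), whereas CBF2 (0.21 ± 0.19, adjusted p = 0.583), CBF1 (0.57 ± 0.37) and CBF3 (0.29 ± 0.16) were not called.

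The test called 226 genes, 131 higher and 95 lower (42% lower), and 3513 passed an unadjusted p under 0.05. Median-of-ratios scaling gave 368, 123 higher and 245 lower (66.6% lower). Without any filter on low values 112 were called, and with only the 6 cold libraries in the fit 5. The count fell to 101 without control replicate 1, 84 without control replicate 3, 123 without cold once replicate 2, 17 without cold once replicate 3, 39 without repeated cold replicate 1, 131 without repeated cold replicate 2 and 112 without repeated cold replicate 3.

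Among the largest rises were AT2G44240 (3.02 ± 0.57), AT1G21520 (2.14 ± 0.34), the C1 domain gene AT2G44380 (1.95 ± 0.27), the defensin-like AT3G05727 (1.89 ± 0.34), ALMT5, of the malate transporter family (1.88 ± 0.23), AT3G14280 (1.81 ± 0.20) and the transcription factor gene WRKY60 (1.79 ± 0.33). Large falls were those of the aspartyl protease gene AT4G16563 (-2.46 ± 0.36), AT4G36850 (-2.43 ± 0.41), the anion channel gene SLAH3 (-2.02 ± 0.29), AT1G35140 (-1.89 ± 0.35), DIN10 (-1.79 ± 0.34) and ERD5 (-1.74 ± 0.25). With each library left out in turn, 2 of 25 named genes were called in all 9 fits, ELIP2 and AT3G14280, and both lost their calls with only the 6 libraries compared, where EXPA8, RD29A, AT1G35140 and AT4G36850 kept theirs. With an immunity gene score as a covariate AT2G44240, AT3G05727, AT4G36850, AT1G35140, DIN10, ERD5, CYP707A1, GSTF12, TT5, P5CS2, BBX32, AT2G30600 and KAT5 were not called, and with a floral marker score AT2G44240, DIN10 and P5CS2 were not. EXPA8, EXLA1 and ALMT5 lost their calls without cold once replicate 3 alone (adjusted p = 0.0683, 0.0668 and 0.0668). AT2G44380 lost its call without cold once replicate 3 or repeated cold replicate 1 (up to 0.0731), AT4G16563 also without repeated cold replicate 2 (up to 0.0757), and ERD5 and SLAH3 without cold once replicate 3 or repeated cold replicate 1 or 3 (up to 0.0802 and 0.0749). AT1G21520 lost it in 4 fits, without control replicate 3, cold once replicate 3 or repeated cold replicate 1 or 2 (up to 0.105), and GSTF12 in 4, without cold once replicate 2 or 3 or repeated cold replicate 1 or 3 (up to 0.12). RD29A lost it in 6 fits, without control replicate 3, cold once replicate 1 or 3, or any repeated cold library (up to 0.114). The calls of AT2G44240, AT3G05727, WRKY60, AT4G36850, AT1G35140 and DIN10 were lost in at least 7 of 9 fits (up to 0.156): without cold once replicate 2 or 3 or any repeated cold library for all 6, and without control replicate 1 (all but AT4G36850), control replicate 2 (AT2G44240 and WRKY60), control replicate 3 (all but AT1G35140) or cold once replicate 1 (AT4G36850, AT1G35140 and DIN10).

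**Figure D5:**
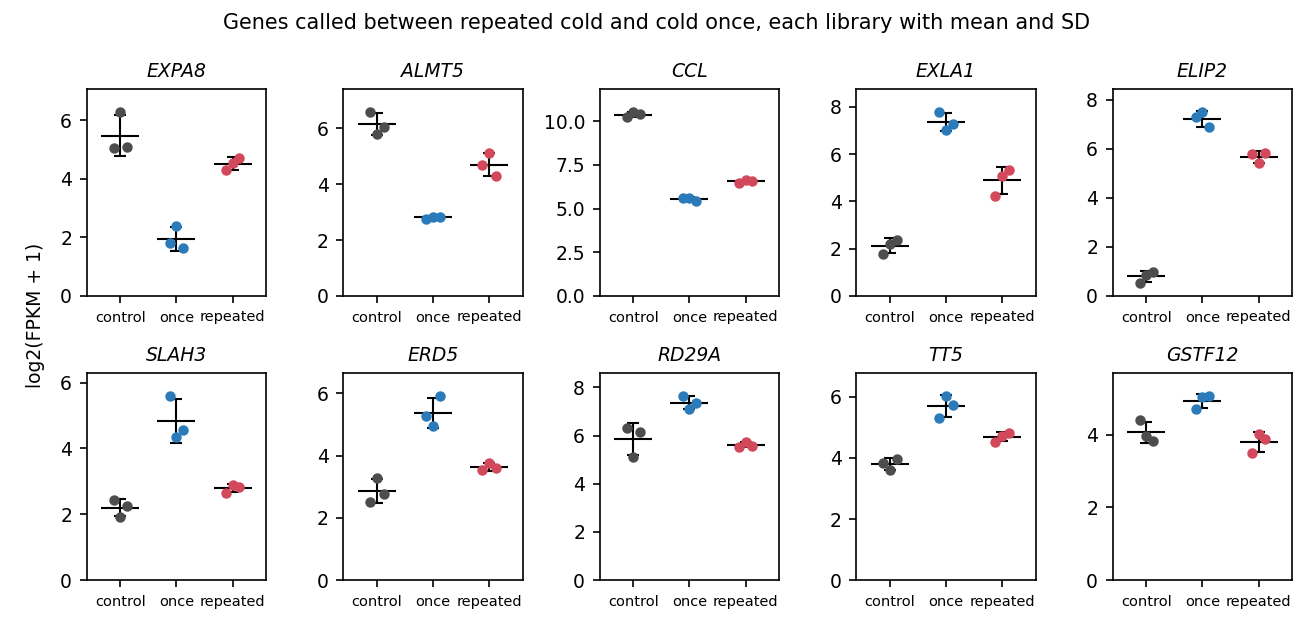
Levels of 10 genes called between repeated cold and cold once as log2(FPKM + 1), each point a library, with group mean (bar) and SD. ELIP2 stood at 0.757, 150 and 50.2 FPKM in control, cold once and repeated cold, and EXPA8 at 47.2, 2.94 and 22.

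Of 14 flavonoid genes, none was higher and 2 were lower (9 adjusted over the list alone), with a median at -0.80 relative to all genes (camera adjusted p = 1.02e-07, and adjusted p = 0.252 with an estimated correlation). TT5 fell by 1.00 ± 0.18 and GSTF12, which carries anthocyanins to the vacuole, by 1.14 ± 0.19, and TT4 was at 177 ± 32.7 FPKM against 370 ± 46.7 in cold once (-1.06 ± 0.24, adjusted p = 0.0667). TT5's call was lost without control replicate 1 or 3, cold once replicate 2 or 3, or any repeated cold library (up to 0.137). None of 8 ribosome biogenesis genes was called (4 lower adjusted over the list alone), with a median at -0.37 relative to all genes (adjusted p = 8.43e-06, and adjusted p = 0.252 with an estimated correlation). FIB2 was at -0.74 ± 0.15. Median-of-ratios scaling called 2 ribosome biogenesis genes lower. Jasmonate genes gave no call among 12 (1 lower adjusted over the list alone), with a median at -0.79 (adjusted p = 1.04e-04, and adjusted p = 0.364 with an estimated correlation). Of 20 cold-regulated effectors 1 was lower, RD29A (2 higher and 3 lower adjusted over the list alone), with a median at -0.30 (adjusted p = 0.00162, and adjusted p = 0.303 with an estimated correlation). Redox genes gave 1 lower of 11, ELIP2 (3 adjusted over the list alone), with adjusted p = 0.0039, and adjusted p = 0.252 with an estimated correlation. Sugar, proline and starch genes gave 2 lower of 10, ERD5 and P5CS2, of proline breakdown and synthesis (1 higher and 2 lower adjusted over the list alone), with adjusted p = 0.0239, and adjusted p = 0.303 with an estimated correlation. P5CS2 (-0.62 ± 0.12) was not called in any fit with 1 of the 9 libraries left out (control, cold once or repeated cold replicate 1, 2 or 3), with adjusted p up to 0.127.

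Among 11 growth genes 1 was higher, EXPA8 (4 adjusted over the list alone), with a median 0.37 above all genes (adjusted p = 0.0221, and adjusted p = 0.252 with an estimated correlation). EXPA1, another expansin, was at 142 ± 30.3 FPKM against 49.7 ± 11.7 (adjusted p = 0.0614). None of 14 immunity genes was called (0 adjusted over the list alone), with a median 0.78 above all genes (adjusted p = 0.00162, and adjusted p = 0.666 with an estimated correlation). PAD4 was at 1.04 ± 0.36 and SARD1 at 1.45 ± 0.52. The growth and sugar lists lost their calls without repeated cold replicate 2 or 3 (adjusted p up to 0.137), and the immunity list without cold once replicate 2 (0.0666). Under quantile normalization the cold-regulated (adjusted p = 0.0548), redox (0.074) and sugar lists (0.14) were not called.

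In the other 11 lists camera's adjusted p lay between 0.0752 and 0.987. No CBF regulator was called (1 higher and 1 lower adjusted over the list alone), although quantile normalization called 1 lower. No clock, photosynthesis, heat shock, H3K4, root, flower or reference gene was called either way (0 adjusted over each list alone). Touch genes gave no call (1 higher and 1 lower adjusted over the list alone), nor did Polycomb and flowering genes (1 lower adjusted over the list alone), with FT at 0.74 ± 0.692 FPKM in repeated cold against 2.76 ± 0.582 in cold once (-1.18 ± 0.26, adjusted p = 0.0649), which quantile normalization called. The abscisic acid list held 1 lower gene (1 higher and 2 lower adjusted over the list alone), CYP707A1 at -1.19 ± 0.21, and RD26 (-0.75 ± 0.17) was called under median-of-ratios scaling. CYP707A1's call was lost without any 1 cold once library or repeated cold replicate 1 or 3 (up to 0.135). Without subtracting the median of all genes, median and mean differed in sign for the abscisic acid list (0.03 and -0.07), and camera pointed down where both lay above 0 for photosynthesis, heat shock, touch and reference genes. Relative to all genes the medians of the abscisic acid, photosynthesis and reference lists were -0.02, -0.05 and -0.01.

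Grouped by both tests, 85 genes that had risen in cold once and 114 that had fallen moved back toward control in repeated cold, 199 together, where independent lists would give 62. Movement further from control was called for 3 genes, where independent lists would give 56. These were BBX32, a B-box factor (0.92 ± 0.16), AT5G55620 (0.64 ± 0.10) and AT2G30600 (-1.21 ± 0.20). Another 24 genes, 15 higher and 9 lower, were called between cold once and repeated cold without a call in cold once against control, among them WRKY60, DIN10 and KAT5, a thiolase gene (-1.37 ± 0.23). Calls were lost with a library left out for BBX32 (control replicate 1 or 3, any cold once library, repeated cold replicate 1 or 2, adjusted p up to 0.124), AT5G55620 (control replicate 3, cold once replicate 1 or 3, repeated cold replicate 1 or 3, up to 0.12), AT2G30600 (control replicate 3, cold once replicate 1 or 3, any repeated cold library, up to 0.109) and KAT5 (control replicate 1 or 3, cold once replicate 2 or 3, repeated cold replicate 1 or 3, up to 0.114). No difference between the cold groups was called for 3227 genes that rose and 5849 that fell in cold once. The cold-once libraries enter both tests with opposite sign, so independent lists are no fair expectation for either count. Part of the excess of genes moving back, and of the lack of genes moving further, may come from chance values of those libraries. Across genes the changes correlated with r = -0.49 where simulated unchanged groups gave -0.50, with a covariance of -0.13 against -0.02. The 199 became 320 under median-of-ratios scaling, 99 without a filter and 4 with only the 6 libraries of each comparison in the fit. It fell to 89 without control replicate 1, 78 without control replicate 3, 100 without cold once replicate 2, 17 without cold once replicate 3, and 37, 114 and 101 without repeated cold replicate 1, 2 and 3. Response classes over repetition were counted by the same rule in each case.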

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

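Tests chosen after their result was seen were those of the clock genes and of the share of the 10 most abundant genes, and the test on changes of at least 1 on the log2 scale was added once the share over all calls was known. Of the genes named for a comparison with control, 9 were also called between the cold groups, a test of the difference between their cold responses, and most of these calls depended on single libraries. The photoprotection gene ELIP2 was lower after repetition (-1.55, adjusted p = 0.0124), as were RD29A (-1.73, adjusted p = 0.0314), the proline dehydrogenase gene ERD5 (-1.74, adjusted p = 0.0195) and the proline synthesis gene P5CS2 (-0.62, adjusted p = 0.0447). So were AT1G35140 (-1.89, adjusted p = 0.042), CYP707A1 (-1.19, adjusted p = 0.0337) and chalcone isomerase TT5, which decreased by 1.00 (adjusted p = 0.0362). EXPA8 (2.58, adjusted p = 0.0126) and CCL (1.00, adjusted p = 0.0111) were higher. ELIP2 kept its call with each library left out in turn and lost it with only the 6 libraries compared, and P5CS2 lost it in all 9 such fits (adjusted p up to 0.127). AT1G35140 and TT5 lost theirs in 7 of 9 fits, RD29A in 6, CYP707A1 in 5, ERD5 in 3 and EXPA8 in 1, and CCL was not followed through these fits.

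Splits of the libraries into other groups gave these values. For each pair of groups the 6 libraries allow 10 splits, too few for a share under 0.05. The real split gave 9278 genes for cold once against control (highest other 0), 7013 for repeated cold against control (highest other 37) and 226 for repeated cold against cold once (highest other 0). For any difference among 3 groups, 1 of 100 splits (the real one and 99 drawn), the real one, gave as many as 8762 genes, so a chance arrangement was argued against. The highest other, 7299, kept the 3 control libraries together and mixed the cold libraries, which points to the separation of control from both cold groups.

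Clock genes moved in both cold groups, with LHY up by 5.31 and CCA1 by 3.61 in cold once. A different hour of sampling in control and cold plants could move them, and for some pairs of hours would lower evening-phased genes while dawn-phased genes rise. The 6 evening-phased genes had a median change of 0.92 with a bootstrap standard error over genes of 0.81 (3 called higher, 1 lower), beside 3.99 for the 4 dawn-phased genes. This spread leaves the hour undecided, and since the labels give no hour, it and the cold treatment cannot be told apart for these genes. The same limit holds for other changes against control, such as that of RVE2, a relative of CCA1 and LHY. An effect of cold on the clock stays open and untested.

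More genes were lower than higher in cold once. Depth was argued against, since 64.2% of calls stayed lower with reads thinned to 1 total. The share of summed FPKM in the 10 most abundant genes differed by -0.04 percentage points between cold once and control. This argued against those few genes taking more of the reads. A shift of reads toward a broader set of abundant genes was not tested. Scaling stays undecided: the lower share was 49.4% of all calls with median-of-ratios scaling, and 49.7% among changes of at least 1 on the log2 scale (64.8% as deposited), but centring the median moves both shares, so neither decides. Whether total mRNA per plant differed was not tested.

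Along the direction from control to cold once, repeated-cold libraries lay at 81.4% of the cold-once response on average. Directions ran from single control to single cold-once libraries, each left out of its group mean (76.1% to 84.8% over 9 directions). Scaling as the whole cause was argued against, since the highest direction reached at most 87.3% with both scalings. So was lower depth as the whole cause, at 84.6% with thinned reads. Leaving out either repeated-cold library that stood apart, replicate 1 with organelle reads or replicate 2 with floral markers, gave at most 87.7%. All 3 stayed under 100%. A response of equal size in a somewhat different direction would also lie under 100% on this line. A weaker response after repetition is therefore a hypothesis that these values cannot decide. Day and plant age differ with group, so they stay open and untested.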

How the results depend on the processing

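Chosen after the data were seen were voom, thinned reads, the floral and immunity covariates, and all recounts of the response classes. Calls in cold once against control, repeated cold against control and among the 3 groups stayed within 1.5 times under every setting run except the minimum of 1 on the log2 scale, which by construction left 2666 and 1855 (78 in repeated cold against cold once). With 1 library left out they ranged from 7598 to 9967, 5237 to 6980 and 6577 to 9641. The 226 genes changed, repeated cold against cold once, became 112 without a filter, 368 with median-of-ratios scaling and 5 with only the 6 libraries compared, and 17 to 208 with 1 library left out. The recount of response classes over repetition gave 99, 320 and 4 for the 199 genes moving back, and 17 to 183 with 1 library left out. Of 18 list calls 0 held with an estimated correlation, and 15 to 20 were made with 1 library left out. The causes were not tested, except that fewer samples enter the fits with left-out libraries and that of 6. No named value reversed. Among named-gene values, 2325 kept direction and side of the threshold in other planned settings, 42 gained and 62 lost a call. With 1 library left out these were 2239, 27 and 188, and in added settings 1043, 14 and 35. For list values they were 535, 2 and 27 in planned settings and 498, 6 and 9 with 1 library left out. Between the cold groups fry's adjusted p was 0.0359 for flavonoid and 0.0344 for ribosome biogenesis, redox and growth genes. It was 0.302 for immunity, 0.261 for jasmonate and 0.185 for cold-regulated and sugar genes. Against control fry called every list that camera called, and also redox in both comparisons and growth, touch and reference genes in cold once.

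The labels do not say that replicate numbers pair the samples, and whether they do stays open: deviations of same-numbered libraries correlated between -0.11 and 0.46, and 6 of 9 libraries correlated best with their own number, a hint from the data and not the design. With the number as a replicate block, 704 genes were called in repeated cold against cold once (473 higher and 231 lower), 10054 and 7988 against control, and 578 moved back in the response classes over repetition. The jasmonate list was then not called in repeated cold against control, and no other list or named call was lost.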

Other observations

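Gene Ontology terms, all tested after the data were seen, were counted first among genes called in cold once against control. The exact test, across 695 terms, takes genes as independent, so its p-values can be too small where genes move together. Of 18 list calls above, 0 held with an estimated correlation between genes. Terms were counted on calls without further scaling, and the split into higher and lower calls depended on scaling. Translation stood out among genes that rose, 175 of 346 where 68.8 would be expected (exact test, adjusted p = 1.54e-35). Chloroplast organization (59 of 123, where 24.5 would be expected) and response to cold (97 of 270, where 53.7 would be expected, adjusted p = 9.24e-08) followed, with ribosomal small subunit assembly at 22 of 31 and rRNA processing at 40 of 83. Genes that fell were enriched for protein ubiquitination (150 of 301, where 98.7 would be expected, adjusted p = 3.09e-07), autophagy (30 of 42, where 13.8 would be expected, adjusted p = 1.14e-04), glucosinolate biosynthesis (18 of 25, adjusted p = 0.00949), fatty acid beta-oxidation (22 of 34, adjusted p = 0.0156) and starch catabolism (12 of 16).

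After 4 cycles translation (121 of 346, where 52.3 would be expected, adjusted p = 8.17e-18) and response to cold (85 of 270, adjusted p = 1.97e-09) were again enriched among genes that rose, with circadian rhythm (35 of 95, adjusted p = 2.07e-05) and the reductive pentose-phosphate cycle of carbon fixation (14 of 22). The hour of sampling stays open for the circadian term as well. Glucosinolate biosynthesis (18 of 25, adjusted p = 5.44e-04), autophagy (23 of 42) and ubiquitination (107 of 301) were enriched among genes that fell. Between the cold groups, response to karrikin, a smoke-derived germination signal, was enriched among genes lower after repetition, 6 of 88 (adjusted p = 0.0125). That term rests on few genes, since 5 genes in all were lower without cold once replicate 3 and 3 with only the 6 libraries compared.

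Genes of the chloroplast and mitochondrial genomes took 0.669% of summed FPKM in repeated cold replicate 1 and 0.087% to 0.118% in the other 8 libraries. Replicates were not copies of one another: the chi-square per gene between libraries of a group ran from 11.36 to 41.26.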
